A study of Mus musculus with 12 samples.

How the data were processed

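The series measured messenger RNA in live CD11c-enriched dendritic cells taken on day 7 of culture from the bone marrow of wild-type C57BL6 mice. Its 4 groups were control cells (BMDC), control cells with LPS, cells treated with vitamin D3 and IL-10 (TolDC), and treated cells with LPS, with 3 libraries in each. Per the labels, RNA was purified with the ISOLATE II RNA Mini Kit and libraries were made with the Illumina Stranded mRNA Prep Ligation kit. The dose of LPS, the length of the stimulation and the doses of vitamin D3 and IL-10 are not given in the sources used here. The deposited values are raw counts per gene, which the authors made by trimming reads with cutadapt and aligning and counting them with STAR against mouse genome mm10 (GRCm38). The processing notes also name edgeR and limma. They give no versions, annotation or settings, and the deposited values were not normalized.

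Each of the 12 tables holds whole numbers in 3 count columns, read without regard to strand (column 2) or on each strand (columns 3 and 4). Column 4, with a total 35.2 to 37.3 times that of column 3 in every library, was used in the main tests. Column 2 was used as an alternative and column 3 only to check the strand. Of 31054 gene identifiers, 31011 were matched to GENCODE M21 for symbols, positions and biotypes. Between 79.3% and 80.6% of the reads counted in a table were assigned to genes, with 9.34% to 9.85% matching several places, 7.10% to 8.01% outside genes, 1.04% to 1.18% ambiguous and 1.52% to 2.11% unmapped. Reads that match several places were left out of the counts by the aligner, so levels in families of near-identical genes are uncertain. The 12 libraries held 21844405 to 41764975 assigned reads. At these depths a gene with no counts in the 3 libraries of a group was below 0.0298 to 0.0415 CPM at the floor of 3 counts over the group. Folds of genes with at most 3 counts in a group were computed from the counts. Against a group with no counts they are lower bounds at that floor, and otherwise ratios with a 95% counting interval.

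Genes were filtered with filterByExpr on the 4 groups, which left 13141, and libraries were scaled with TMM factors between 0.945 and 1.04. A quasi-likelihood model with robust dispersion estimates was fitted to all 12 libraries with a mean per group (edgeR 4.0.16, R 4.3.3). In that model the 4 groups share the estimate of the spread. The biological coefficient of variation was 0.0572. The 5 contrasts were LPS in BMDC, LPS in TolDC, TolDC against BMDC without LPS and with LPS, and the difference between the LPS responses. P-values were adjusted by Benjamini-Hochberg within a contrast and genes called at an adjusted p below 0.05. Calls with at least a 2-fold change were counted as well. The groups, contrasts, tests, gene lists and the rule for naming genes were chosen before the data were examined.

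Lists of genes (22 lists of functions and 13 of markers of cell types and handling, written from general knowledge) were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over all 175 tests. Camera asks whether a list moved relative to all other genes. It was repeated with the correlation estimated from the data, a harder test. With it, 10 of the 55 list calls held. These were inflammatory cytokines (adjusted p = 0.00809), co-stimulation and NF-kB genes (both 0.0335) and oxidative stress genes (0.0421) for LPS in BMDC, inflammatory cytokines (0.00809) and NF-kB and oxidative stress genes (both 0.0335) for LPS in TolDC, co-stimulation (0.0468) and cholesterol synthesis (0.0423) for TolDC without LPS, and co-stimulation (0.0124) for TolDC with LPS. Fry, the other alternative, asks whether the members of a list moved in themselves, whatever the rest of the genes did. Counts of called members are given from the adjustment over all genes and, as "adjusted over the list alone", from an adjustment over the members only. Some genes belong to several lists.

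The genes named in the text are, for each contrast, the 8 largest rises and the 8 largest falls among called genes without overlap between the libraries compared (a condition dropped for the difference between responses) and with at least 5 CPM in the higher group. Unnamed and predicted genes, pseudogenes and antigen receptor segments were skipped. To these were added the called members with at least 5 CPM and the largest change, up to 3 for each list described, or the most abundant member where none was called, and 14 genes fixed by name. Some genes that this rule selects are left out of the text. Any other gene is said to have been chosen after its values were seen. Percentages of variance come from principal components of the log2 CPM values. The number in a library's name was not used as a pair or block. Deviations from the group means were correlated between libraries with the same number in different groups, and 1 of 18 such pairs fell below 0.1 (0.091), short of the rule that all exceed it. The block was tried as an alternative.

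The model was tested on simulated data with 200 changed genes among 13141, of which 50 were at each fold. At 1.2, 1.5, 2 and 4-fold it found 46%, 76%, 78% and 94% for LPS in BMDC and 28%, 70%, 72% and 86% for the difference between responses, with 6 and 7 false calls. Alternatives covered RLE factors, DESeq2 1.42.0, limma-voom, no low-count filter and a filter of 5 CPM in 3 libraries, counts of both strands, fits to the compared groups alone, the block, each library left out, and for lists the other list tests. Further alternatives were added after the data were seen. These were a fit without the 4 libraries numbered 1, a fit with libraries 2 and 3 of a group summed, and the removal of each library's trend with GC content and transcript length. Every alternative was run, except that a fit to compared groups alone does not exist for the difference between responses. Protein levels and T cell responses were not analysed here.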

Results

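Gene expression was measured by RNA sequencing in dendritic cells, the antigen-presenting cells that start or restrain T cell responses, grown from the bone marrow of C57BL6 mice. On day 7 of culture, live cells carrying CD11c, an integrin chain used to recognise dendritic cells, had been enriched. Control cells (BMDC) were compared with tolerogenic cells (TolDC), which had been treated with vitamin D3 and interleukin 10 (IL-10). Both were studied with and without lipopolysaccharide (LPS), a component of bacterial cell walls that is recognised through Toll-like receptor 4. The series concerns tolerogenic dendritic cells in protection from acute kidney injury. It held 12 libraries, 3 in each of the 4 groups. The reads assigned to genes numbered 27518662, 30007479 and 22605855 in BMDC replicates 1, 2 and 3 and 29811533, 21844405 and 22538627 in BMDC with LPS. They numbered 24614813, 23699310 and 27422956 in TolDC, and 32422014, 30397084 and 41764975 in TolDC with LPS. At these depths, 3 counts in a library corresponded to between 0.0718 and 0.137 CPM, which are counts scaled to a common library total. Chil3, which encodes a chitinase-like protein of myeloid cells and was chosen after its values were seen, was the most abundant transcript in all 12 libraries, with 3.09% to 8.84% of the counts. Levels are given below as mean CPM ± SD with n = 3 libraries per group, and log2 changes ± SE. Nothing in the labels says that replicates came from separate cultures or animals, so the p-values measure the spread between these samples, which may be technical.

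The libraries separated by LPS and by cell type. The leading principal component held 50.9% of the variance and parted all 6 LPS libraries from all 6 unstimulated libraries. The next held 36.2% and parted TolDC from BMDC. The fourth component, with 2.75% of the variance, parted the library numbered 1 of each group from those numbered 2 and 3. In those 4 libraries, transcripts of granulocytes, which are other cells of the bone marrow, were lower. S100a9, a calcium-binding protein abundant in neutrophils, was at 130.2 CPM in BMDC replicate 1 and at 709.3 and 684.9 CPM in replicates 2 and 3. It was at 21.9 CPM in TolDC replicate 1 and at 145.7 and 143.4 CPM in replicates 2 and 3. Mcpt8, a mast cell and basophil protease, was at 6.32, 24.6 and 24.1 CPM in the same BMDC libraries and at 9.99, 56.6 and 57.5 CPM in the TolDC libraries. Both genes were chosen after their values were seen. The edgeR log2 difference of the libraries numbered 1 from the others, over all groups, was −2.24 for S100a9 and −2.34 for Mcpt8 (edgeR adjusted p = 9.72e-05 and 1.94e-08).

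**Figure D1:**
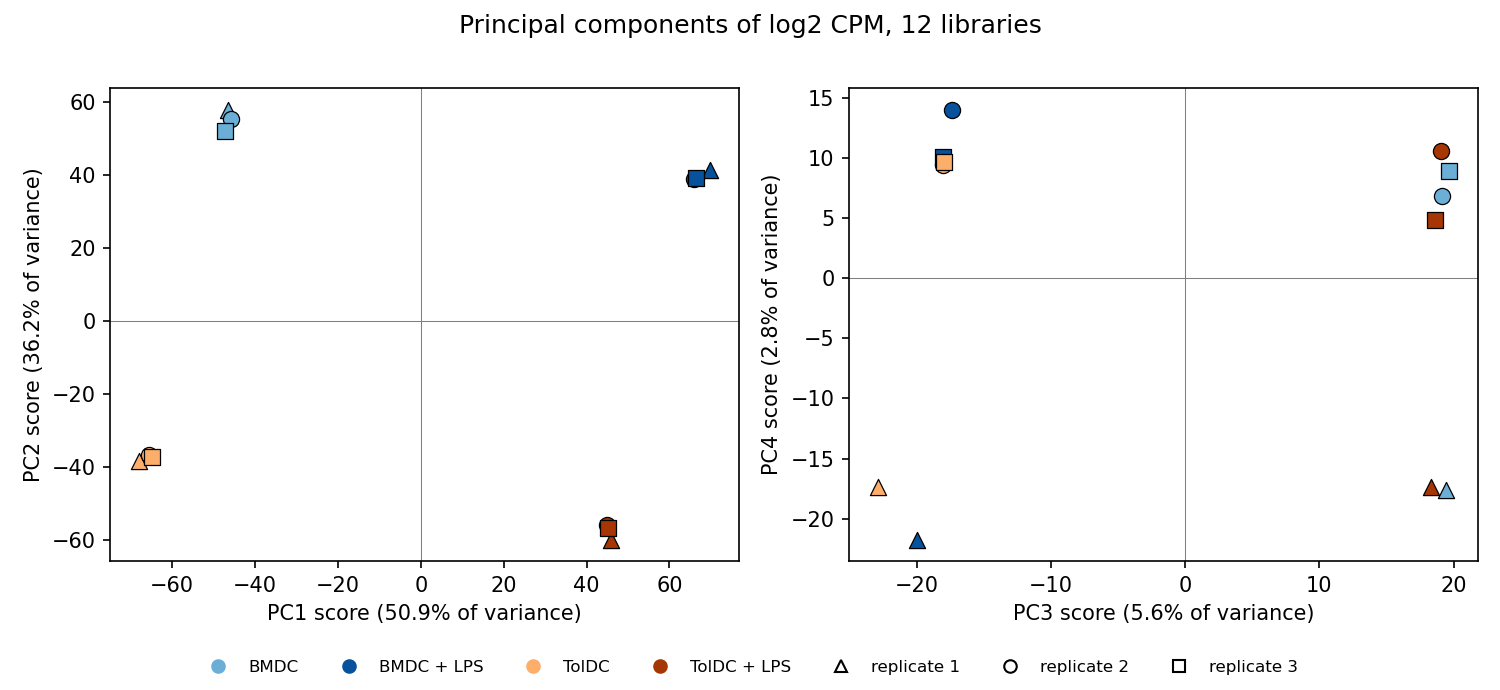
Principal components of the log2 CPM values of the 12 libraries, with the share of variance on each axis; each point is a library, its colour the group and its shape the replicate. The 6 LPS libraries lie on the positive side of the component with 50.9% of the variance, and the libraries numbered 1 lie apart from the other libraries of their groups on the component with 2.75%.

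**Figure D2:**
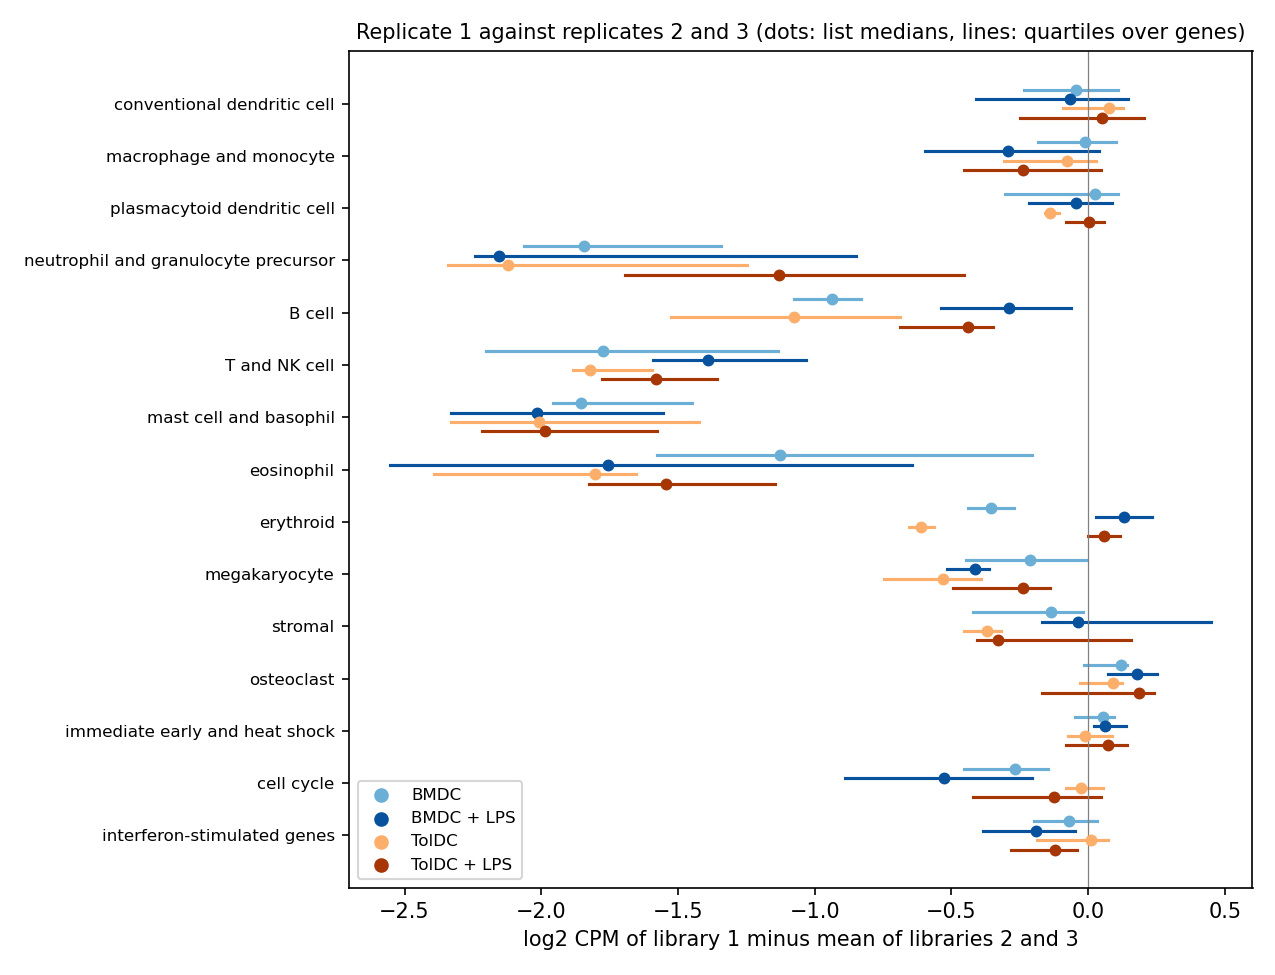
Log2 difference between the library numbered 1 and the mean of those numbered 2 and 3, in each of the 4 groups, for lists of marker genes; dots are the medians over the members of a list and lines their quartiles. The neutrophil list had medians of −1.84 in BMDC, −2.15 in BMDC with LPS, −2.12 in TolDC and −1.13 in TolDC with LPS, against −0.069, −0.19, 0.011 and −0.12 for interferon-stimulated genes in that order.

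In BMDC, the response to LPS was led by inflammatory mediators. Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis (ENSMUSG00000032487, chromosome 1, 150100031 to 150108227 of GRCm38, plus strand, protein coding), rose from 0.633 ± 0.161 to 591 ± 52.1 CPM. Saa3, an acute-phase protein (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700, minus strand), rose from 0.423 ± 0.191 to 717 ± 128 CPM. Il12b, which encodes the p40 chain shared by IL-12 and IL-23 (ENSMUSG00000004296, chromosome 11, 44400063 to 44414033, plus strand), rose from 0.870 ± 0.04996 to 185 ± 18.1 CPM. The cytokines Il6 and Tnf rose from 4.90 ± 0.658 to 463 ± 11.6 CPM and from 27.8 ± 1.68 to 294 ± 18.6 CPM. Among the genes that fell were surface receptors. Ccr2, the receptor that draws monocytes to sites of inflammation (ENSMUSG00000049103, chromosome 9, 124101950 to 124113557, plus strand), went from 1050.2 ± 46.5 to 46.5 ± 1.22 CPM. Mrc1, the mannose receptor (ENSMUSG00000026712, chromosome 2, 14229392 to 14332057, plus strand), went from 439 ± 37.8 to 14.5 ± 2.81 CPM.

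Further large rises in BMDC were those of Lox, which cross-links collagen (log2 change 9.44 ± 0.32), Cxcl1, a neutrophil-attracting chemokine (8.82 ± 0.16), and Il12a, the p35 chain of IL-12 (8.67 ± 0.22). These fitted values rest on few unstimulated counts. Without BMDC replicate 1 they were 10.94 for Lox and 9.58 for Cxcl1, without the 4 libraries numbered 1 they were 11.08 and 9.55, and without BMDC replicate 2 that of Il12a was 9.53. Il1f6, an IL-36 cytokine, and Csf3, the granulocyte growth factor, had no counts in unstimulated BMDC and were at least 391-fold higher and at least 288-fold higher with LPS, against a floor of 3 counts over the group. Krt16, a keratin, was 262-fold higher (95% counting interval 72.3 to 2174). Further large falls were those of Nxpe5 (log2 change −5.46 ± 0.30), Slco2b1, an organic anion transporter (−5.42 ± 0.19), Fcrls, a scavenger and Fc receptor-like protein (−5.01 ± 0.086), Clec4b1 (−4.48 ± 0.10) and Mgl2 (−4.22 ± 0.058), which are C-type lectins, and Fn1, the matrix protein fibronectin (−4.36 ± 0.16).

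All 23 inflammatory cytokines and effectors tested rose in BMDC, the same counts adjusted over the list alone. The inflammatory list had a median log2 change of 5.36 (camera adjusted p = 7.92e-11, and adjusted p = 0.00809 with an estimated correlation). With Ifnb1 and Csf3, which were at the floor without LPS, placed at their lower bounds, the median was 4.98. Among chemokines, 17 of 22 rose and 4 fell, with 1 not called and 17 higher and 5 lower adjusted over the list alone. The chemokine list had a median log2 change of 1.49 (camera adjusted p = 5.29e-04, and adjusted p = 0.215 with an estimated correlation). Cxcl2, another attractant of neutrophils, went from 2.80 ± 0.544 to 312 ± 1.93 CPM, and Cxcl10, an interferon-induced attractant of T cells, from 0.359 ± 0.120 to 29.3 ± 8.54 CPM. Co-stimulation and maturation genes, through which dendritic cells activate T cells, included 15 that rose, 1 that fell and 3 not called, the same counts adjusted over the list alone. The co-stimulation list had a median log2 change of 1.74 (camera adjusted p = 1.36e-05, and adjusted p = 0.0335 with an estimated correlation). Cd40, the receptor for CD40 ligand on T cells (ENSMUSG00000017652, chromosome 2, 165055627 to 165072948, plus strand), rose from 8.67 ± 0.531 to 416 ± 26.4 CPM. Slamf1 rose from 14.6 ± 0.529 to 203.9 ± 17.9 CPM, and Marcksl1, an actin-binding protein, from 87.9 ± 10.2 to 852 ± 21.8 CPM. The CD28 ligands Cd80 and Cd86 rose by 1.63 ± 0.045 and 1.87 ± 0.042 on the log2 scale, and Ccr7, which guides dendritic cells to lymph nodes, by 1.74 ± 0.072.

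Interferon-stimulated genes rose in BMDC in 38 of 40 cases, with 2 not called and the same counts adjusted over the list alone. The interferon-stimulated list had a median log2 change of 1.88 (camera adjusted p = 3.42e-12, and adjusted p = 0.201 with an estimated correlation). The antiviral genes Oasl1 and Rsad2 rose from 9.59 ± 0.645 to 370.3 ± 16.5 CPM and from 12.2 ± 0.0438 to 384 ± 32.5 CPM. Irf7, a transcription factor of the interferon response, rose from 8.95 ± 3.61 to 255 ± 38.9 CPM. Of 22 genes of NF-kB and its feedback regulators, 19 rose, 1 fell and 2 were not called, 20 higher and 1 lower adjusted over the list alone. The NF-kB list had a median log2 change of 1.63 (camera adjusted p = 1.25e-08, and adjusted p = 0.0335 with an estimated correlation). The largest of these rises were in Nfkbiz (log2 change 4.97 ± 0.076), Traf1 (3.06 ± 0.042) and Zc3h12a, an RNase that limits cytokine transcripts (2.60 ± 0.046). Oxidative stress and NRF2 genes, which protect cells from oxidants, rose in 20 of 26 cases and fell in 4, with 2 not called and the same counts adjusted over the list alone. Their median log2 change was 0.66 (camera adjusted p = 3.57e-04, and 0.0421 with an estimated correlation). They included Sod2, the mitochondrial superoxide dismutase (log2 change 2.59 ± 0.051), Nqo1 (2.47 ± 0.092) and Fth1, the ferritin heavy chain (2.12 ± 0.044).

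Genes of mitochondrial metabolism and of cell division fell in BMDC with LPS. Of 40 nuclear genes of oxidative phosphorylation, 36 fell, 1 rose and 3 were not called, the same counts adjusted over the list alone. Their median log2 change was −0.46 (camera adjusted p = 2.20e-08, and 0.220 with an estimated correlation). Log2 changes were −0.95 ± 0.039 for Ndufs1, −0.81 ± 0.038 for Sdhc and −0.72 ± 0.046 for Ndufb5. For the tricarboxylic acid cycle and fatty acid oxidation, 28 of 31 fell, 1 rose and 2 were not called, the same counts adjusted over the list alone. Their median log2 change was −0.61 (camera adjusted p = 6.32e-07, and 0.312 with an estimated correlation). Idh2, the mitochondrial isocitrate dehydrogenase, went from 85.2 ± 3.79 to 24.98 ± 2.12 CPM. Suclg2 went from 12.4 ± 1.21 to 3.98 ± 0.741 CPM and Acaa2 from 107 ± 1.68 to 41.8 ± 1.18 CPM. Cell cycle genes fell in 28 of 32 cases and rose in 3, with 1 not called and the same counts adjusted over the list alone. Their median log2 change was −1.31 (camera adjusted p = 8.57e-05, and 0.592 with an estimated correlation). The mitotic cyclins Ccnb1 and Ccnb2 went from 11.1 ± 1.97 to 2.36 ± 0.494 CPM and from 11.5 ± 2.22 to 2.67 ± 0.976 CPM. Cenpf, a kinetochore protein, went from 7.87 ± 1.29 to 1.73 ± 0.450 CPM.

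Over all genes, edgeR's quasi-likelihood test called 4825 of 13141 genes higher and 4789 lower with LPS in BMDC, of which 1472 and 1444 changed at least 2-fold. Vdr, the vitamin D receptor, changed by −0.20 ± 0.069 (edgeR adjusted p = 0.0169), a call lost without BMDC replicate 1 (−0.15) or without BMDC with LPS replicate 2 (−0.16) or 3 (−0.18), or with the libraries numbered 2 and 3 summed (−0.20). Cd274, which encodes the inhibitory ligand PD-L1, rose by 2.18 ± 0.036. Clec4b1 has near-identical relatives, and reads that matched several places were left out of the counts, so its level is uncertain.

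In TolDC, LPS also raised inflammatory mediators, while single receptors fell. Saa3 rose from 0.911 ± 0.194 to 2622 ± 228 CPM and Cxcl1 from 0.123 ± 0.109 to 69.9 ± 0.207 CPM. Hamp, the iron-regulating hormone hepcidin, rose from 0.532 ± 0.122 to 162 ± 20.8 CPM. Cxcl2 rose from 3.82 ± 1.15 to 611 ± 1.52 CPM and Lox by 7.66 ± 0.36 on the log2 scale. Mrc1 fell from 182 ± 12.2 to 5.30 ± 0.657 CPM and Cxcr2, the receptor of neutrophil-attracting chemokines, from 192 ± 4.602 to 7.94 ± 2.80 CPM. The value of Cxcl1, 9.04 ± 0.15 on the log2 scale, was 10.07 without TolDC replicate 3. Il1f6, with no counts in unstimulated TolDC, was at least 349.9-fold higher with LPS, Csf3 was 1327-fold higher (95% counting interval 238 to 52450.0), and Cfb, complement factor B, 208-fold higher (95% counting interval 70.9 to 1011). The log2 change of Csf3, 9.94, was 9.25 with limma-voom, 11.89 without TolDC replicate 1 and 11.95 without the 4 libraries numbered 1. The other large falls were in Kcnq3, a potassium channel (log2 change −5.84 ± 0.31), Clec4b1 (−5.12 ± 0.14), Rnase6, a ribonuclease of innate defence (−5.03 ± 0.084), Tnfaip8l3 (−4.78 ± 0.13), Ccdc80 (−4.69 ± 0.11) and Slco2b1 (−4.49 ± 0.17).

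Inflammatory cytokines and effectors rose in TolDC in 21 of 23 cases, with 1 fall and 1 not called, and 22 higher and 1 lower adjusted over the list alone. The inflammatory list had a median log2 change of 4.09 (camera adjusted p = 2.13e-09, and adjusted p = 0.00809 with an estimated correlation). With Ifnb1 and Csf3 at their lower bounds, the median was 3.68. Il23a, the p19 chain of IL-23, rose by 6.23 ± 0.23 on the log2 scale (6.93 without TolDC replicate 1). Il12b rose from 0.129 ± 0.0616 to 8.73 ± 0.189 CPM, Il6 from 3.85 ± 1.38 to 280.4 ± 11.7 CPM and Tnf from 49.6 ± 2.60 to 239 ± 23.4 CPM. Of 19 co-stimulation and maturation genes, 13 rose, 3 fell and 3 were not called, the same counts adjusted over the list alone. The co-stimulation list had a median log2 change of 1.201 (camera adjusted p = 0.00210, and adjusted p = 0.0710 with an estimated correlation). Cd40 rose from 2.34 ± 0.363 to 81.4 ± 3.73 CPM, Marcksl1 from 17.2 ± 4.67 to 428 ± 7.72 CPM and Slamf1 from 5.17 ± 0.957 to 89.6 ± 5.47 CPM. Cd80 and Cd86 rose by 0.48 ± 0.045 and 0.45 ± 0.050 on the log2 scale and Ccr7 by 1.94 ± 0.076. Interferon-stimulated genes rose in 34 of 40 cases and fell in 2, with 4 not called and the same counts adjusted over the list alone. Their median log2 change was 1.35 (camera adjusted p = 1.19e-08, and 0.296 with an estimated correlation). Oasl1 rose from 3.02 ± 0.415 to 81.1 ± 6.91 CPM and Rsad2 from 5.85 ± 0.469 to 116 ± 8.66 CPM. Ifit1, which binds viral RNA, rose from 3.41 ± 0.401 to 56.3 ± 7.01 CPM.

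Genes around the IL-10 receptor and its transcription factor STAT3 rose in TolDC in 17 of 20 cases and fell in 3, the same counts adjusted over the list alone. Their median log2 change was 0.94 (camera adjusted p = 1.37e-05, and 0.136 with an estimated correlation). In BMDC 17 of 20 rose and 2 fell, with a median log2 change of 1.002 (camera adjusted p = 4.35e-06, and 0.130 with an estimated correlation). The difference between the responses had a median of −0.023 (camera adjusted p = 0.733). In TolDC, Socs3, a feedback inhibitor of cytokine signalling, rose from 38.5 ± 2.51 to 668 ± 6.10 CPM. Il1rn, the antagonist of the IL-1 receptor, rose from 166 ± 9.54 to 961 ± 69.3 CPM, and Hmox1, haem oxygenase, from 737 ± 15 to 3233 ± 266 CPM. Il10 itself had no counts in unstimulated TolDC and was at 0.473 ± 0.165 CPM with LPS, at least 12.7-fold higher. Among 30 genes of TLR4 and other pattern receptors, 20 rose, 6 fell and 4 were not called, with 20 higher and 7 lower adjusted over the list alone. Their median log2 change was 0.58 (camera adjusted p = 0.00475, and 0.137 with an estimated correlation). Clec4e, a receptor of mycobacterial glycolipids, rose by 6.86 ± 0.17 on the log2 scale, and Tlr2, which recognises bacterial lipoproteins, by 2.61 ± 0.16. Cd14, the co-receptor of TLR4 for LPS, rose from 35.0 ± 2.12 to 669.7 ± 18.1 CPM. Genes of MHC class I presentation rose in 13 of 22 cases and fell in 4, with 5 not called and the same counts adjusted over the list alone. Their median log2 change was 0.34 (camera adjusted p = 0.00923, and 0.386 with an estimated correlation). They were led by Cybb, the NADPH oxidase subunit of phagosomes (log2 change 3.06 ± 0.058), and the class I genes H2-Q7 (2.02 ± 0.060) and H2-Q4 (1.91 ± 0.047), which are near-identical and therefore uncertain.

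All 32 cell cycle genes fell in TolDC with LPS, the same counts adjusted over the list alone. Their median log2 change was −2.72 (camera adjusted p = 7.92e-11, and 0.304 with an estimated correlation). Cenpf went from 11.4 ± 1.27 to 0.715 ± 0.376 CPM. Ccna2, a cyclin of DNA replication and mitotic entry, went from 34.6 ± 0.932 to 2.45 ± 0.604 CPM, and Kif20a, a kinesin of cell division, from 22.99 ± 0.229 to 2.10 ± 0.210 CPM. edgeR called 4651 genes higher and 4719 lower, of which 1267 and 1396 changed at least 2-fold. Vdr changed by −1.01 ± 0.069 on the log2 scale and Cd274 rose by 1.89 ± 0.036. Cyp24a1, the enzyme that inactivates vitamin D, went from 1757 ± 57.1 to 573 ± 47.9 CPM, without overlap (1708 to 1820 and 533 to 626). The log2 change of −1.62 ± 0.67 did not pass (edgeR adjusted p = 0.0692). Its spread was shared with BMDC, at 0, 0.0324 and 13.1 CPM without LPS. The change passed with the replicate block, limma-voom and a fit of these groups alone (all −1.62), but not with libraries 2 and 3 summed. It also passed without the libraries numbered 1 (−1.66), or BMDC replicate 1 (−1.62) or 3 (−1.61), which act through the shared spread.

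Genes called in the same direction in both cell types numbered 3531 for rises and 3501 for falls, where independent lists of these sizes would share 1708 and 1720. A further 363 genes rose in BMDC and fell in TolDC, and 269 did the opposite. Across the 13141 genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.80 and a Spearman correlation of 0.76. The comparisons share no libraries.

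**Figure D3:**
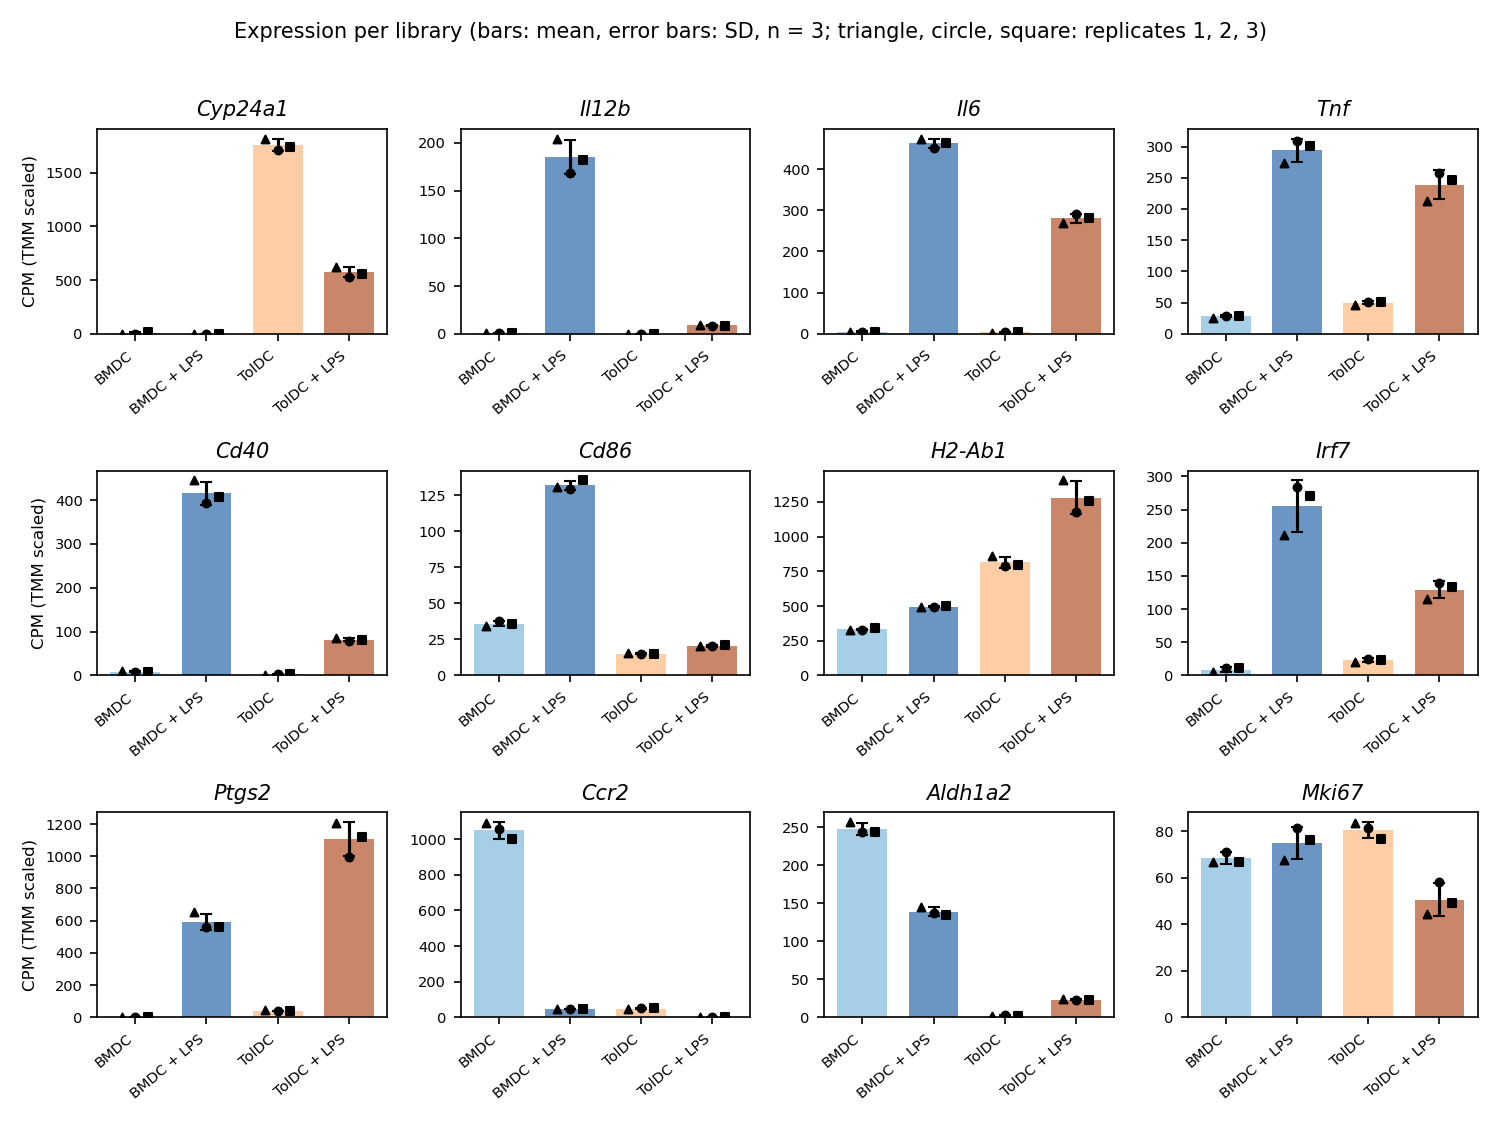
Levels of 12 genes in CPM on a linear axis in the 4 groups; bars are means, error bars SD and points the 3 replicates. Cd86 reached 132 ± 3.11 CPM in BMDC with LPS and 20.5 ± 0.430 CPM in TolDC with LPS, and Cyp24a1 was at 1757 ± 57.1 CPM in TolDC.

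Unstimulated TolDC differed from unstimulated BMDC in co-stimulation, in cholesterol synthesis and in single genes with large differences. Cyp24a1, a direct target of the vitamin D receptor (ENSMUSG00000038567, chromosome 2, 170482708 to 170497145 of GRCm38, minus strand, protein coding), was at 1757 ± 57.1 CPM in TolDC and at 0, 0.0324 and 13.1 CPM in BMDC replicates 1, 2 and 3. Its fitted log2 difference of 8.83 was 16.31 without BMDC replicate 3, 8.22 without BMDC replicate 1 and 8.17 without BMDC replicate 2. It was 13.23 with limma-voom and 8.24 without the 4 libraries numbered 1. Aldh1a2, the retinal dehydrogenase that makes retinoic acid (ENSMUSG00000013584, chromosome 9, 71215789 to 71296243, plus strand), was lower, from 248 ± 7.84 to 1.98 ± 0.397 CPM, and Ccr2 from 1050.2 ± 46.5 to 49.0 ± 2.58 CPM. Cd86 (ENSMUSG00000022901, chromosome 16, 36603869 to 36666081, minus strand) was lower, from 35.99 ± 1.55 to 15.03 ± 0.376 CPM. H2-Ab1, a chain of MHC class II, was higher, from 331 ± 6.69 to 814 ± 38.04 CPM.

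Other genes far higher in TolDC were Tgfb3, a transforming growth factor (log2 difference 8.87 ± 0.14), Chga, the secretory granule protein chromogranin A (8.23 ± 0.20), and Msi1, an RNA-binding protein of stem cells (7.56 ± 0.20). Without BMDC replicate 3 these were 9.26 for Chga and 8.17 for Msi1. Scara5, a ferritin receptor, had no counts in BMDC and was at least 328-fold higher in TolDC. Klk13, a kallikrein protease, was 1121-fold higher (95% counting interval 200.8 to 44320.0), Iqsec3 458-fold higher (95% counting interval 126 to 3789), and Lhx6, a homeobox factor, 225-fold higher (95% counting interval 61.9 to 1863). The log2 difference of Klk13, 9.68, was 9.01 with limma-voom, 11.56 without BMDC replicate 1 and 11.49 without the 4 libraries numbered 1, and that of Iqsec3, 8.59, was 8.002 without BMDC replicate 2 and 11.28 without BMDC replicate 3. The genes far lower in TolDC included the kallikreins Klk15 (log2 difference −6.66 ± 0.20, and −5.58 with both strands counted) and Klk1b26 (−5.54 ± 0.21, of a near-identical family and so uncertain). Others were Mucl1, a mucin-like protein (−6.95 ± 0.23), Ms4a8a (−6.09 ± 0.20), Dclk1, a microtubule-associated kinase (−5.55 ± 0.17), the non-coding Mir9-3hg (−5.29 ± 0.25) and Tcaf2 (−4.79 ± 0.10).

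Of 12 genes of the vitamin D receptor and its targets, 5 were higher and 5 lower in TolDC, with 2 not called and the same counts adjusted over the list alone. The vitamin D list had a median log2 difference of 0.078 (camera adjusted p = 0.867). Hbegf, a growth factor of the epidermal growth factor family, was higher, from 63.3 ± 2.93 to 306 ± 11.6 CPM, and Vdr from 324 ± 19.2 to 516 ± 25.7 CPM. Rxra, the partner of the vitamin D receptor on DNA, was lower, from 55.1 ± 1.25 to 21.02 ± 2.08 CPM. Cd14 differed by 0.062 ± 0.052 (edgeR adjusted p = 0.311). Co-stimulation and maturation genes were lower in TolDC in 15 of 19 cases and higher in 3, with 1 not called and the same counts adjusted over the list alone. The co-stimulation list had a median log2 difference of −1.19 (camera adjusted p = 5.29e-04, and adjusted p = 0.0468 with an estimated correlation). Cd83, a maturation marker, went from 152 ± 0.769 to 25.8 ± 0.361 CPM, and Marcksl1 from 87.9 ± 10.2 to 17.2 ± 4.67 CPM. Cd40 went from 8.67 ± 0.531 to 2.34 ± 0.363 CPM and Ccr7 from 179.7 ± 13.7 to 50.01 ± 5.83 CPM. Cd80 differed by −0.14 ± 0.045 on the log2 scale, a call lost without TolDC replicate 2 (−0.13) or 3 (−0.12), with the libraries numbered 2 and 3 summed (−0.15), and with the trends of GC content and length removed (−0.058). In MHC class II presentation, 12 of 16 genes were higher and 2 lower, 2 were not called, and there were the same counts adjusted over the list alone. The class II list had a median log2 difference of 0.43 (camera adjusted p = 0.00183, and adjusted p = 0.402 with an estimated correlation). H2-Ob and H2-DMb2, which are also in this list, were higher by 2.64 ± 0.093 and 1.36 ± 0.075 on the log2 scale.

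All 22 cholesterol synthesis genes were lower in TolDC, the same counts adjusted over the list alone. The cholesterol synthesis list had a median log2 difference of −0.74 (camera adjusted p = 1.37e-09, and adjusted p = 0.0423 with an estimated correlation). Idi1 was lower, from 9.58 ± 0.176 to 2.48 ± 0.0840 CPM, Sc5d from 45.99 ± 1.53 to 19.7 ± 0.0351 CPM, and Cyp51 from 44.2 ± 1.40 to 21.2 ± 2.04 CPM. Genes of glycolysis and the hypoxia response were higher in 20 of 25 cases and lower in 4, with 1 not called and the same counts adjusted over the list alone. The glycolysis and hypoxia list had a median log2 difference of 0.35 (camera adjusted p = 2.89e-04, and adjusted p = 0.302 with an estimated correlation). Bnip3, a hypoxia-induced mitophagy receptor, was higher by 1.32 ± 0.055 on the log2 scale, while Pfkfb4 and Pfkp, which act at the phosphofructokinase step, were lower, with log2 differences of −1.16 ± 0.051 and −1.16 ± 0.071. Cell cycle genes were higher in 22 of 32 cases and lower in 1, with 9 not called and the same counts adjusted over the list alone. The cell cycle list had a median log2 difference of 0.41 (camera adjusted p = 0.00649, and adjusted p = 0.801 with an estimated correlation). Among them were Mcm5, of the replicative helicase (log2 difference 0.91 ± 0.15), Kif20a (0.75 ± 0.13) and Ccnb2 (0.65 ± 0.20), the last of which did not pass with the libraries numbered 2 and 3 summed (0.72).

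Complement, Fc and scavenger receptor genes were lower in TolDC in 16 of 27 cases and higher in 6, with 5 not called and the same counts adjusted over the list alone. The complement and scavenger list had a median log2 difference of −0.92 (camera adjusted p = 0.0277, and adjusted p = 0.162 with an estimated correlation), and it did not pass among genes with at least 5 CPM in 3 libraries (median −0.36). Clec10a, a lectin for galactose-type sugars, went from 43.8 ± 4.32 to 6.34 ± 0.621 CPM. C1qc and C1qb, of the complement component that binds immune complexes, went from 8.64 ± 1.03 to 1.27 ± 0.470 CPM and from 14.4 ± 1.41 to 2.91 ± 0.359 CPM. Of 18 macrophage and monocyte markers, 10 were lower, 4 higher and 4 not called, the same counts adjusted over the list alone. The macrophage marker list had a median log2 difference of −1.12 (camera adjusted p = 0.0327, and adjusted p = 0.389 with an estimated correlation), and it did not pass without BMDC replicate 3 (median −1.07). Ccr2, C1qc and C1qb led this list too. Chemokine and migration receptors were higher in 7 cases and lower in 8 of 19, with 4 not called and the same counts adjusted over the list alone. The migration receptor list had a median log2 difference of 0.0095 (camera adjusted p = 0.841) and a mean of −0.012. Ccr2 and Ccr7, whose levels are given above, were among the lower genes.

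Inhibitory and tolerogenic molecules went both ways in TolDC, with 10 of 30 higher, 15 lower and 5 not called, the same counts adjusted over the list alone. The inhibitory molecule list had a median log2 difference of −0.21 (camera adjusted p = 0.469). With Il10, which was under the floor in both groups, left out, the median was −0.20. Gpnmb, a glycoprotein of macrophages and dendritic cells that restrains T cells, was higher, from 697 ± 36.9 to 2343 ± 123 CPM, and Cd274 from 266 ± 4.61 to 326 ± 6.72 CPM. Aldh1a2 was lower. So were Lgals1, the lectin galectin 1, from 329.8 ± 6.38 to 113 ± 2.32 CPM, and Ido1, an enzyme of tryptophan breakdown, from 2.18 ± 0.472 to 0.334 ± 0.0208 CPM. Il10 had 1 count in BMDC and none in TolDC, under the floor, so no difference was detectable at this depth. Conventional dendritic cell markers were higher in 5 and lower in 7 of 14 cases, with 2 not called and the same counts adjusted over the list alone. The dendritic cell marker list had a median log2 difference of −0.44 (camera adjusted p = 0.486). Btla, an inhibitory receptor, went from 0.814 ± 0.611 to 69.3 ± 1.96 CPM (log2 difference 6.49 ± 0.21, and 7.16 without BMDC replicate 3). Kit, the stem cell factor receptor, went from 1.81 ± 0.115 to 22.3 ± 1.14 CPM. Neutrophil and granulocyte precursor markers were lower in 7 and higher in 2 of 16 cases, with 7 not called and 2 higher and 4 lower adjusted over the list alone. The neutrophil marker list had a median log2 difference of −1.27 (camera adjusted p = 0.486). It passed with the replicate block (median −1.28) or without the 4 libraries numbered 1 (−1.26), but not with the libraries numbered 2 and 3 summed, and with all libraries it had an adjusted p = 0.975 with an estimated correlation. Mmp8, neutrophil collagenase, was higher, from 53.3 ± 7.21 to 460.0 ± 5.22 CPM. The granule proteases Elane and Prtn3 were lower, with log2 differences of −3.995 ± 0.86 and −3.09 ± 0.65 (−5.52 for Elane without TolDC replicate 3), and neither passed with the libraries numbered 2 and 3 summed (−3.87 and −2.96). These are among the markers that were lower in the libraries numbered 1 of every group.

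edgeR called 4203 genes higher and 3998 lower in unstimulated TolDC than in BMDC, of which 853 and 1055 differed at least 2-fold. The value of Cyp24a1 and those of the genes with under 4 counts in BMDC are set by single libraries or by the floor, and intervals and floors cover counting error only.

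With LPS, TolDC were below BMDC in co-stimulation and in the p40 chain of IL-12. Cd86 was at 132 ± 3.11 CPM in BMDC and at 20.5 ± 0.430 CPM in TolDC. Cd40 was at 416 ± 26.4 and 81.4 ± 3.73 CPM, and Il12b at 185 ± 18.1 and 8.73 ± 0.189 CPM. Higher in TolDC were Pdgfa, a growth factor for mesenchymal cells, at 8.39 ± 0.801 CPM in BMDC and 307 ± 31.4 CPM in TolDC, and Mmp13, a collagenase. Mmp13 (ENSMUSG00000050578, chromosome 9, 7272514 to 7283331 of GRCm38, plus strand, protein coding) was at 10.96 ± 1.15 and 198 ± 10.8 CPM. Cyp24a1 had no counts in BMDC with LPS and was at 573 ± 47.9 CPM in TolDC with LPS, at least 13790.0-fold higher.

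The genes that differed most under LPS were in part those that differed without it. Msi1, with no counts in BMDC with LPS, was at least 457-fold higher in TolDC, Chga 994-fold higher (95% counting interval 178 to 39270.0), and Iqsec3 744-fold higher (95% counting interval 133 to 29430.0). The log2 difference of Iqsec3, 9.13, was 4.98 with both strands counted, 8.41 with limma-voom, 11.15 without BMDC with LPS replicate 1 and 11.10 without the 4 libraries numbered 1. That of Chga, 9.55, was 8.77 with both strands counted, 8.83 with limma-voom and 11.61 without BMDC with LPS replicate 3. Cdr2l was higher by 7.81 ± 0.21 on the log2 scale (8.79 without BMDC with LPS replicate 3), and Robo4, an endothelial guidance receptor, by 6.83 ± 0.27 (8.72 without BMDC with LPS replicate 1, and 6.20 with both strands counted). Pde10a, a phosphodiesterase, was higher by 6.78 ± 0.16 and Tgfb3 by 6.61 ± 0.21. In the other direction, Klk15 was 727-fold lower (95% counting interval 129.8 to 28750.0). Its log2 difference of −8.97 was −9.69 with both strands counted, −8.38 with limma-voom and −10.59 without TolDC with LPS replicate 3. Log2 differences were −7.05 ± 0.16 for Mucl1, −5.76 ± 0.26 for Adra2a, an adrenergic receptor, −5.72 ± 0.17 for Amelx, the enamel protein amelogenin, and −5.03 ± 0.095 for Tcaf2. Klk1b26 (−5.66 ± 0.23, and −6.37 without TolDC with LPS replicate 3) and Klk1b8 (−5.30 ± 0.25) were lower too and belong to a near-identical family, so that their levels are uncertain.

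Of 19 co-stimulation and maturation genes, 18 were lower in TolDC with LPS and 1 not called, and all 19 were lower adjusted over the list alone. The co-stimulation list had a median log2 difference of −1.10 (camera adjusted p = 5.81e-08, and 0.0124 with an estimated correlation). The log2 differences were −2.69 ± 0.044 for Cd86, −2.61 ± 0.045 for Cd83, −2.35 ± 0.054 for Cd40, −1.64 ± 0.072 for Ccr7 and −1.28 ± 0.044 for Cd80. Conventional dendritic cell markers were lower in 10 of 14 cases and higher in 4, the same counts adjusted over the list alone. This list had a median log2 difference of −1.005 (camera adjusted p = 0.0528, and 0.217 with an estimated correlation). It passed with the replicate block (−0.998), GC content and length trends removed (−1.03) or no low-count filter (−1.34). With libraries 2 and 3 summed it did not. It also passed without the 4 libraries numbered 1 (−0.94), TolDC replicate 1 (−1.002) or BMDC with LPS replicate 3 (−1.06). The same held without TolDC with LPS replicate 1 (−1.05), 2 (−0.95) or 3 (−1.02). Interferon-stimulated genes were lower in 36 of 40 cases and higher in 1, with 3 not called and the same counts adjusted over the list alone. This list had a median log2 difference of −0.81 (camera adjusted p = 1.25e-08, and 0.296 with an estimated correlation). Ifit2 was at 85.0 ± 12.4 CPM in BMDC and 14.9 ± 3.69 CPM in TolDC, Oasl1 at 370.3 ± 16.5 and 81.1 ± 6.91 CPM. Ifi205, of a family of near-identical genes and so uncertain, was at 55.1 ± 4.72 and 3.17 ± 0.111 CPM. Inflammatory cytokines and effectors went both ways, with 14 of 23 lower, 7 higher and 2 not called, the same counts adjusted over the list alone. Their median log2 difference was −0.49 (camera adjusted p = 0.312). Lower were Tnfsf15, a T cell co-stimulator, with a log2 difference of −6.04 ± 0.13, Il12b with −4.41 ± 0.068, Il23a with −2.52 ± 0.10, Il6 with −0.72 ± 0.11 and Tnf with −0.30 ± 0.068.

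MHC class II presentation genes were higher in TolDC with LPS in 13 of 16 cases and lower in 3, the same counts adjusted over the list alone. Their median log2 difference was 0.53 (camera adjusted p = 0.00172, and 0.402 with an estimated correlation). H2-Ab1 was at 496 ± 3.29 CPM in BMDC and 1279.7 ± 117 CPM in TolDC. Log2 differences were 1.57 ± 0.086 for H2-Ob and 1.44 ± 0.077 for H2-DMb2. Matrix, protease and growth factor genes were higher in 18 of 30 cases and lower in 6, with 6 not called and the same counts adjusted over the list alone. The matrix and protease list had a median log2 difference of 0.46 (camera adjusted p = 0.0233, and adjusted p = 0.185 with an estimated correlation). The largest differences were those of Mmp8 (5.65 ± 0.10), Pdgfa (5.18 ± 0.19) and Mmp13 (4.17 ± 0.062). Of 29 apoptosis genes, 20 were lower, 6 higher and 3 not called, the same counts adjusted over the list alone. Their median log2 difference was −0.19 (camera adjusted p = 0.0307, and 0.215 with an estimated correlation). Pmaip1, which promotes cell death, and Bcl2l1, which opposes it, were lower, with log2 differences of −1.99 ± 0.046 and −1.15 ± 0.049, and Bcl2, another survival gene, was higher by 0.78 ± 0.13. Cell cycle genes were lower in 26 of 32 cases and not called in 6, the same counts adjusted over the list alone. The cell cycle list had a median log2 difference of −0.93 (camera adjusted p = 1.49e-05, and adjusted p = 0.546 with an estimated correlation). It was led by the cyclins Ccne2 (−2.18 ± 0.11) and Ccne1 (−1.74 ± 0.070) and by Rrm2, which makes the building blocks of DNA (−1.58 ± 0.20). Cholesterol synthesis genes were lower in 15 of 22 cases and higher in 2, with 5 not called and the same counts adjusted over the list alone. The cholesterol synthesis list had a median log2 difference of −0.40 (camera adjusted p = 7.26e-04, and adjusted p = 0.215 with an estimated correlation). Lower were Idi1 (−2.20 ± 0.089), Stard4 (−1.05 ± 0.064) and Fdft1 (−0.96 ± 0.055).

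edgeR called 4507 genes higher and 4422 lower in TolDC than in BMDC with LPS, of which 900 and 1248 differed at least 2-fold. Vdr differed by −0.13 ± 0.069 (edgeR adjusted p = 0.103). It passed without TolDC with LPS replicate 1 (−0.22) or the libraries numbered 1 (−0.15), and with DESeq2 (−0.15) or the replicate block (−0.13). It did not with libraries 2 and 3 summed. Both without and with LPS, 2726 genes were higher in TolDC and 2637 lower, where independent lists would share 1442 and 1345. A further 503 were higher without LPS and lower with it, and 405 the opposite. The log2 differences had Pearson and Spearman correlations of 0.75 and 0.62.

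**Figure D4:**
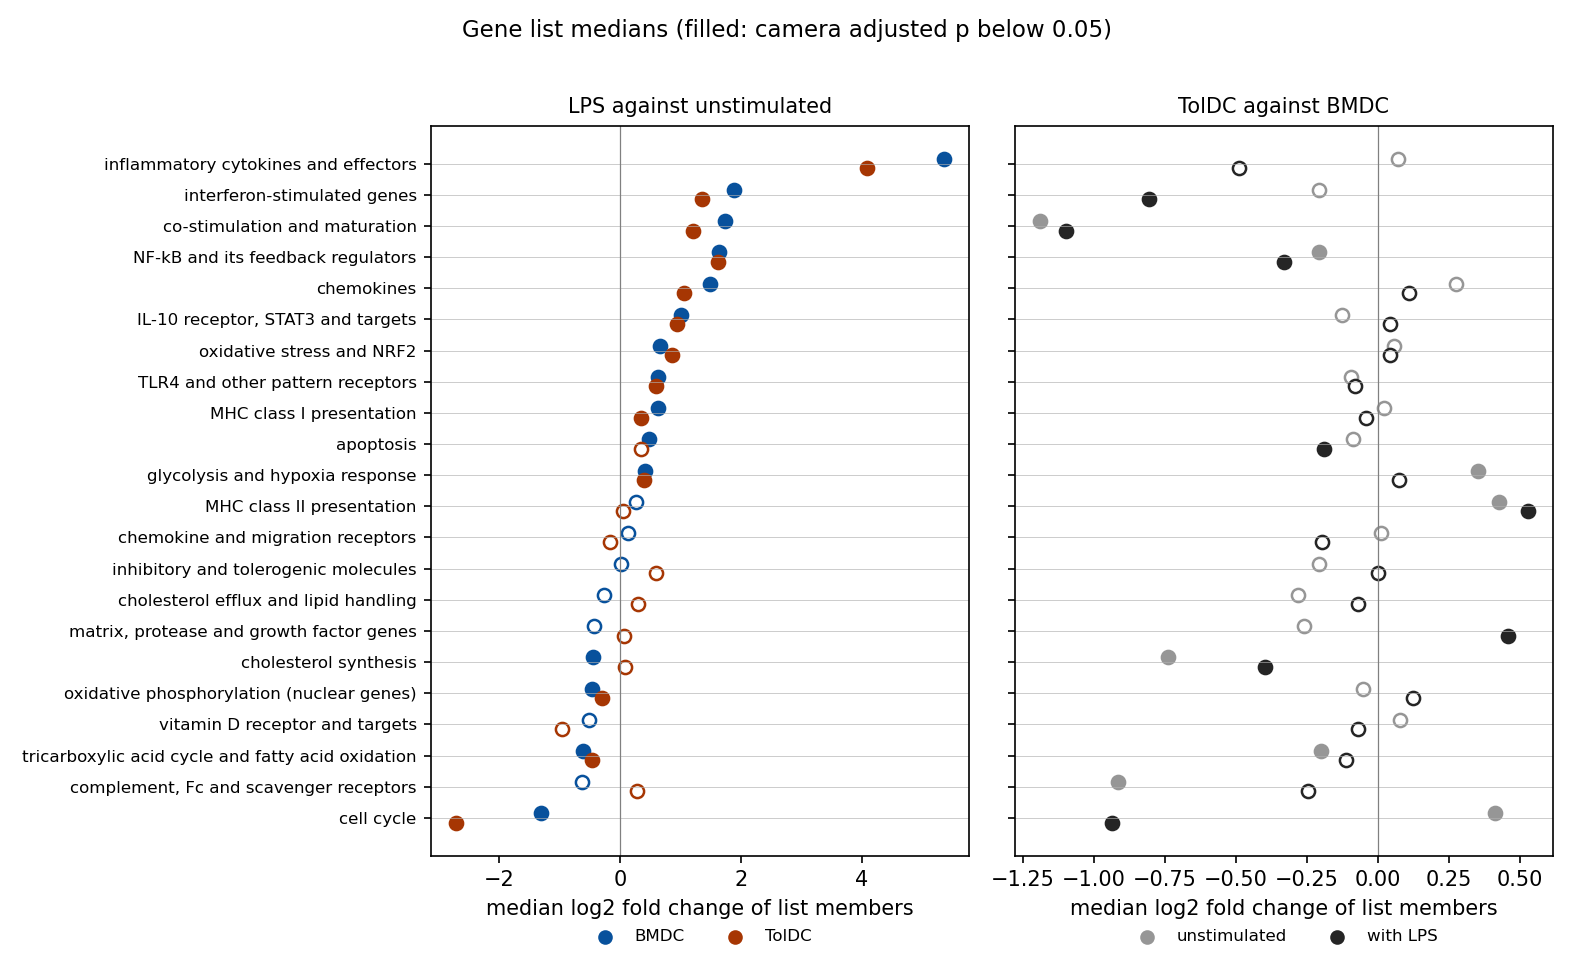
Median log2 changes of 22 gene lists, a list per line; filled points passed camera at an adjusted p below 0.05. The left panel gives LPS against no stimulation in BMDC and in TolDC, where inflammatory cytokines had medians of 5.36 and 4.09, and the right panel gives TolDC against BMDC without and with LPS, where cholesterol synthesis had medians of −0.74 and −0.40.

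Whether the LPS response itself differed between the cell types was tested as the change in TolDC minus the change in BMDC. The response of Ptgs2 was smaller in TolDC on the log2 scale, from 0.633 ± 0.161 to 591 ± 52.1 CPM in BMDC and from 39.4 ± 2.31 to 1109 ± 104 CPM in TolDC, although its level with LPS was higher in TolDC. Igsf9, an immunoglobulin superfamily adhesion molecule (ENSMUSG00000037995, chromosome 1, 172481788 to 172498878 of GRCm38, plus strand, protein coding), moved in opposite directions, from 30.7 ± 2.52 to 87.5 ± 3.13 CPM in BMDC and from 69.3 ± 3.49 to 8.17 ± 0.168 CPM in TolDC. So did Mmp13, from 28.9 ± 0.960 to 10.96 ± 1.15 CPM in BMDC and from 11.01 ± 0.0843 to 198 ± 10.8 CPM in TolDC, and Aldh1a2, from 248 ± 7.84 to 139 ± 5.47 CPM in BMDC and from 1.98 ± 0.397 to 23.3 ± 0.316 CPM in TolDC. Cd86 went from 35.99 ± 1.55 to 132 ± 3.11 CPM in BMDC and from 15.03 ± 0.376 to 20.5 ± 0.430 CPM in TolDC.

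Among the largest positive differences of response were those of Mmp13 (5.56 ± 0.089), Aldh1a2 (4.39 ± 0.10), Hamp (3.96 ± 0.40), Slc28a3, a nucleoside transporter (3.72 ± 0.23), and Clec4a1, a lectin with near-identical relatives and so uncertain (3.06 ± 0.25). That of Ugt1a9, a glucuronosyltransferase (4.41 ± 1.25), was not called without BMDC replicate 2 (4.12) or 3 (3.94) and was 5.57 without TolDC replicate 3. The largest negative differences were those of Ptgs2 (−5.07 ± 0.19), Igsf9 (−4.59 ± 0.083), Tlr11, a receptor of microbial proteins (−4.18 ± 0.32), Igfbp4, which binds insulin-like growth factors (−4.18 ± 0.20), Amelx (−4.17 ± 0.43) and Grap2, an adaptor of immune receptors (−3.93 ± 0.61). Msi1, Krt17, Sprr2d and Iglon5 also passed but had at most 3 counts in a group, so no size is given.

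Inflammatory cytokines and effectors had lower changes in TolDC in 12 of 23 cases and higher in 2, with 9 not called. The counts were the same adjusted over the list alone. The inflammatory list had a median log2 difference of −1.12 (camera adjusted p = 0.00158, and adjusted p = 0.0587 with an estimated correlation). Beside Ptgs2 these included Il12a (−3.52 ± 0.47, and −4.37 without BMDC replicate 2), Tnf (−1.13 ± 0.10), Tnfsf15 (−2.44 ± 0.69, not called without TolDC replicate 2, −2.25) and Il12b (−1.68 ± 0.53, not called without TolDC replicate 1, −1.26, or without the 4 libraries numbered 1, −1.24). Il6 had a difference of −0.39 ± 0.25 (edgeR adjusted p = 0.239), which passed without TolDC replicate 1 (−0.65) or without the 4 libraries numbered 1 (−0.50). Co-stimulation and maturation genes had lower responses in 9 of 19 cases and higher in 3, with 7 not called and the same counts adjusted over the list alone. The co-stimulation list had a median log2 difference of −0.47 (camera adjusted p = 0.0346, and adjusted p = 0.199 with an estimated correlation). Its call was lost without TolDC replicate 1 (median −0.48), without the 4 libraries numbered 1 (−0.46), with limma-voom (−0.46) and among genes with at least 5 CPM in 3 libraries (−0.45). The T cell co-stimulators Tnfsf9 and Tnfsf4 had differences of −1.75 ± 0.16 and −1.44 ± 0.10, Cd86 of −1.43 ± 0.066, Cd80 of −1.15 ± 0.063 and Cd40 of −0.47 ± 0.13. That of Ccr7 was 0.20 ± 0.10 (edgeR adjusted p = 0.132) and passed without BMDC replicate 1 (0.27) or without the 4 libraries numbered 1 (0.13).

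Interferon-stimulated genes had lower responses in TolDC in 29 of 40 cases and 11 were not called, with 0 higher and 30 lower adjusted over the list alone. Their median log2 difference was −0.60 (camera adjusted p = 1.63e-08, and 0.3 with an estimated correlation). Irf7 went from 8.95 ± 3.61 to 255 ± 38.9 CPM in BMDC and from 23.1 ± 3.01 to 129 ± 12.6 CPM in TolDC. Ifi44 and Ifit2 had differences of −2.29 ± 0.43 and −1.73 ± 0.26. Cell cycle genes had lower changes in TolDC in 31 of 32 cases and 1 was not called. Adjusted over the list alone, all 32 were lower. This list fell further in TolDC, with a median log2 difference of −1.36 (camera adjusted p = 5.22e-10, and 0.314 with an estimated correlation). Ccne1, the cyclin of entry into DNA replication, went from 16.4 ± 1.56 to 27.3 ± 0.855 CPM in BMDC and from 20.1 ± 0.745 to 8.18 ± 0.185 CPM in TolDC. The differences of Tk1 and Rrm2, which supply DNA precursors, were −2.07 ± 0.37 (−1.02 with both strands counted) and −1.94 ± 0.25. Immediate early and heat shock genes, which mark rapid stimulation and stress, had lower responses in 8 of 13 cases and 5 were not called, with 0 higher and 9 lower adjusted over the list alone. The immediate early list had a median log2 difference of −0.37 (camera adjusted p = 0.0106, and adjusted p = 0.136 with an estimated correlation). It did not pass among genes with at least 5 CPM in 3 libraries (median −0.34). Egr1 and Junb, immediate early transcription factors, had differences of −1.86 ± 0.10 and −0.91 ± 0.063, and the chaperone Hspa1a of −0.79 ± 0.18, not called with both strands counted (−0.69).

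Matrix, protease and growth factor genes had higher responses in TolDC in 17 of 30 cases and lower in 5, with 8 not called and the same counts adjusted over the list alone. This list had a median log2 difference of 0.45 (camera adjusted p = 8.00e-04, and 0.0587 with an estimated correlation). Mmp8 and Mmp9 had differences of 2.54 ± 0.12 and 2.95 ± 0.65, the latter not called with the libraries numbered 2 and 3 summed (2.99). Cholesterol efflux and lipid handling genes had higher responses in 13 of 20 cases and lower in 5, with 2 not called and the same counts adjusted over the list alone. This list had a median log2 difference of 0.58 (camera adjusted p = 8.00e-04, and 0.215 with an estimated correlation). Abca1, the cholesterol exporter, went from 12.1 ± 1.91 to 38.2 ± 1.67 CPM in BMDC and from 0.757 ± 0.1001 to 17.4 ± 1.78 CPM in TolDC. Ch25h, which makes 25-hydroxycholesterol, and Fabp4, a fatty acid carrier, had differences of 2.55 ± 0.12 and 2.37 ± 0.18. Cholesterol synthesis genes had higher responses in 13 of 22 cases and lower in 2, with 7 not called and 16 higher and 2 lower adjusted over the list alone. This list had a median log2 difference of 0.30 (camera adjusted p = 0.00194, and 0.249 with an estimated correlation). Its median changes were −0.45 in BMDC and 0.079 in TolDC. Higher were Sqle (1.44 ± 0.12), Mvd (0.93 ± 0.077) and Cyp51 (0.87 ± 0.13). For oxidative phosphorylation, 22 of 40 genes had higher responses, 4 lower and 14 were not called, with 23 higher and 4 lower adjusted over the list alone. This list had a median log2 difference of 0.19 (camera adjusted p = 9.07e-04, and 0.455 with an estimated correlation). It fell in both, with medians of −0.46 in BMDC and −0.31 in TolDC. It did not pass with the trends of GC content and length removed (median 0.075). Ndufa2 (0.45 ± 0.072), Ndufa1 (0.44 ± 0.063, not called with those trends removed, 0.18) and Ndufb3 (0.42 ± 0.077) led it.

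Macrophage and monocyte markers had higher responses in 9 of 18 cases and lower in 2, with 7 not called and 9 higher and 3 lower adjusted over the list alone. This list had a median log2 difference of 0.70 (camera adjusted p = 0.0469, and 0.402 with an estimated correlation). This list did not pass without BMDC replicate 1 (median 0.83), 2 (0.56) or 3 (0.57), TolDC replicate 1 (0.44), or TolDC with LPS replicate 2 (0.59) or 3 (0.67). Nor did it pass with the libraries numbered 2 and 3 summed (0.73) or with the trends of GC content and length removed (0.65). Lyz2, lysozyme, went from 4280.2 ± 55.2 to 463 ± 112 CPM in BMDC and from 1542 ± 13.9 to 626 ± 113 CPM in TolDC. Fcgr1, the high-affinity IgG receptor, had a difference of 1.78 ± 0.19. That of Cd14 was −0.17 ± 0.069 (edgeR adjusted p = 0.0517), which passed without BMDC replicate 3 (−0.20), BMDC with LPS replicate 1 (−0.18) or TolDC replicate 1 (−0.22). It also passed with DESeq2, limma-voom or the replicate block and without the 4 libraries numbered 1 (all −0.17). So it did with GC content and length trends removed (−0.25), but not with libraries 2 and 3 summed. Conventional dendritic cell markers had higher responses in 3 of 14 cases and lower in 7, with 4 not called and the same counts adjusted over the list alone. The dendritic cell marker list had a median log2 difference of −0.34 (camera adjusted p = 0.356). Irf8, a transcription factor of dendritic cell development, went from 48.7 ± 3.18 to 167 ± 6.29 CPM in BMDC and from 84.2 ± 3.17 to 52.1 ± 2.50 CPM in TolDC. Btla and Kit had differences of −3.72 ± 0.31 (−4.40 without BMDC replicate 3) and −1.18 ± 0.19.

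edgeR called 2683 genes with a higher and 3151 with a lower change in TolDC, of which 482 and 607 differed at least 2-fold. Of the 3531 genes that rose in both cell types, 997 rose less in TolDC, 560 rose more and 1974 showed no called difference. The 3501 genes that fell in both held 730 that fell further in TolDC, 787 that fell less and 1984 with no called difference. Vdr had a difference of −0.80 ± 0.10.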

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

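Of the tests in this part, the exchange of remainders between groups, the comparison of cell cycle genes with all others, and those in the libraries numbered 1 alone and with the trends of GC content and length removed were chosen after the main results had been seen. The results below are set apart because the LPS response differed between TolDC and BMDC by a test of the difference itself, with 2683 genes higher and 3151 lower in TolDC. Of 100 partitions of the 12 libraries into groups of these sizes, the real one called 5834 genes and the highest of the others 2813. The others mix cell types and LPS within a group, which widens its spread, so this test decides nothing about the difference between responses. In a second test, an additive model of cell type, LPS and replicate number was fitted to the log2 CPM values, and its remainders were exchanged between groups within each replicate number. Of 100 arrangements, the real one called 6657 genes with limma, and the highest of the others called 0. The remainders still hold the difference between responses, which widens the spread of the others, so this test decides nothing either.

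Lower values of the change in TolDC minus the change in BMDC were found by camera in the cell cycle (median log2 difference −1.36), inflammatory (−1.12), interferon-stimulated (−0.60), co-stimulation (−0.47) and immediate early (−0.37) lists. None of these calls held with an estimated correlation (adjusted p = 0.314, 0.0587, 0.3, 0.199 and 0.136 in that order). That of co-stimulation was also lost with limma-voom (median −0.46), among genes with at least 5 CPM in 3 libraries (−0.45), without TolDC replicate 1 (−0.48) and without the 4 libraries numbered 1 (−0.46), and that of immediate early genes under that filter (−0.34). Among cytokines and enzymes of inflammation, the log2 differences were −5.07 for Ptgs2, −3.52 for Il12a, −2.44 for Tnfsf15, −1.68 for Il12b and −1.13 for Tnf. Il12b was not called without TolDC replicate 1 (−1.26) or without the 4 libraries numbered 1 (−1.24), nor Tnfsf15 without TolDC replicate 2 (−2.25). Interferon-stimulated genes were at −2.35 for Irf7, −2.29 for Ifi44 and −1.73 for Ifit2. Ligands and receptors of T cell activation were at −1.75 for Tnfsf9, −1.44 for Tnfsf4, −1.43 for Cd86, −1.15 for Cd80 and −0.47 for Cd40. Egr1, Junb and Hspa1a were at −1.86, −0.91 and −0.79, and Tk1, Ccne1 and Rrm2 at −2.07, −2.03 and −1.94. The other single genes with lower changes in TolDC were Igsf9 (−4.59), Tlr11 (−4.18), Igfbp4 (−4.18), Amelx (−4.17), Grap2 (−3.93), Btla (−3.72), Irf8 (−2.47), Kit (−1.18) and Vdr (−0.80).

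Higher changes in TolDC were found by camera in the macrophage marker (median log2 difference 0.70), cholesterol efflux (0.58), matrix and protease (0.45), cholesterol synthesis (0.30) and oxidative phosphorylation (0.19) lists. None of these calls held with an estimated correlation (adjusted p = 0.402, 0.215, 0.0587, 0.249 and 0.455 in that order). That of oxidative phosphorylation was also lost with the trends of GC content and length removed (median 0.075), and that of macrophage markers with those trends removed (0.65), with the libraries numbered 2 and 3 summed (0.73) and when any 1 of 6 libraries was left out. Matrix proteases were at 5.56 for Mmp13, 2.95 for Mmp9 and 2.54 for Mmp8. Genes of lipid handling were at 2.86 for Abca1, 2.55 for Ch25h and 2.37 for Fabp4, and those of cholesterol synthesis at 1.44 for Sqle, 0.93 for Mvd and 0.87 for Cyp51. Lyz2 and Fcgr1 were at 1.91 and 1.78, and Ndufa2, Ndufa1 and Ndufb3 at 0.45, 0.44 and 0.42. The other genes were Ugt1a9 (4.41), Aldh1a2 (4.39), Hamp (3.96), Slc28a3 (3.72) and Clec4a1 (3.06). Hspa1a was not called with both strands counted (−0.69), Ugt1a9 without BMDC replicate 2 (4.12) or 3 (3.94), Mmp9 with the libraries numbered 2 and 3 summed (2.99), nor Ndufa1 with the trends of GC content and length removed (0.18).

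The larger fall of cell cycle genes in TolDC was weighed against technical causes. The median of the list lay at −1.356 from that of the other 13109 genes (quartiles −1.62 to −0.994), a distance that no scaling factor can change, which argues against the scaling between libraries. After the removal of each library's trend with GC content and transcript length the median was −1.345, which argues against that bias. In the libraries numbered 1 alone, where markers of granulocytes were lower, it was −1.22, but with 1 library per group this decides nothing, and cells of other marrow types stay open. An effect of vitamin D3 and IL-10 on division under LPS, the biological difference that the design names, stays open too and was not tested.

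Reads on the strand opposite to the genes, which the comparisons do not use, made up 2.61% to 2.77% of the reads counted on either strand. This signal was set apart because its count was above 0, and no cause was tested.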

How the results depend on the processing

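The fits without the libraries numbered 1, with libraries 2 and 3 summed and with the GC content and length trends removed, and the 2-fold overlap of the TolDC comparisons, were tests chosen after the results were seen. No gene named in the text that was called in the main fit or in an alternative changed direction between them. Directions of genes called in neither were not compared. Counts stayed within 1.5 times the main value except as follows. A filter of 5 CPM in 3 libraries left 10077 genes, of which 971 and 834 were at least 2-fold higher and lower with LPS in BMDC, 797 and 829 in TolDC, 480 and 528 for TolDC without LPS, and 483 and 689 with LPS. Only 252 had at least 2-fold higher responses in TolDC. At 2-fold in both, the LPS responses shared 1806 genes (896 higher, 910 lower) and the TolDC comparisons 1168 (517 higher, 651 lower). The list tests passed 10 times with an estimated correlation and 127 times with fry, against 55. Camera, relative to other genes, and fry gave opposite directions for the conventional dendritic cell list with LPS in BMDC (median 0.33). The same held in TolDC with LPS for migration receptors (−0.17), complement and scavenger receptors (0.27) and plasmacytoid markers (0.38), and between TolDC and BMDC with LPS for the vitamin D (−0.071) and cholesterol efflux (−0.072) lists. Leaving out each library gave 9221 to 9709 calls for LPS in BMDC, 8862 to 9575 in TolDC, 7542 to 8453 for TolDC without LPS, 8368 to 9106 with LPS and 5244 to 5782 for the difference of responses. The LPS responses then shared 6753 to 7013 genes and the TolDC comparisons 5011 to 5304, with 53 to 57 list calls. Where this left 1 group with 2 libraries, the spread came from all groups. With libraries 2 and 3 summed, 75.4% of the calls of the difference and 86.1% to 92.1% of the others were kept. DESeq2 kept 89.98% to 95.4% and the removal of GC content and length trends 84.8% to 95.7%, with opposite calls for 8 genes in TolDC without LPS and 40 with LPS. Counts of both strands gave opposite calls for 1 to 4 genes per comparison. The replicate block, which is not the main model because 1 of 18 pairs fell below 0.1, lost 13 to 21 calls and gained 372 to 722. In 10 of 12 libraries the closest library of another group carried the same number.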

Other observations

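Of the tests in this part, the test of granulocyte markers in the libraries numbered 1 was chosen only after the result was seen, as were the choice of genes for the test of Cyp24a1 and the fits without those libraries, with libraries 2 and 3 summed and with the trends of GC content and length removed.

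The marker lists described here did not pass camera. Between unstimulated TolDC and BMDC, osteoclast markers went both ways. Of 8 genes, 4 were higher and 4 lower in TolDC, the same counts adjusted over the list alone. Their median log2 difference was −0.71 (camera adjusted p = 0.753). Ctsk, the bone collagen protease cathepsin K, went from 103 ± 4.64 to 8.14 ± 0.490 CPM, and Acp5, the tartrate-resistant acid phosphatase, from 104 ± 7.45 to 14.02 ± 0.618 CPM. Mmp9, a gelatinase, had a log2 difference of −1.65 ± 0.48, which did not pass in the fit of these groups alone (−1.64) or with libraries 2 and 3 summed (−1.70). Of 6 plasmacytoid dendritic cell markers, 2 were higher, 2 lower and 2 not called, the same counts adjusted over the list alone. Their median log2 difference was −0.12 (camera adjusted p = 0.880). The transcription factors Tcf4, Spib and Runx2 differed by 1.46 ± 0.078, −1.87 ± 0.16 and −0.53 ± 0.068. Of 9 T and NK cell markers 1 was higher in TolDC and 8 were not called, the same counts adjusted over the list alone. Their median log2 difference was 0.90 (camera adjusted p = 0.516). The called gene was Il7r, the IL-7 receptor (0.52 ± 0.082).

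The libraries numbered 1 differed from the others in 1159 higher and 852 lower genes, of which 5 and 288 differed at least 1.5-fold. The highest median of the neutrophil, mast cell and eosinophil lists over the 4 groups was −1.13 (quartiles −1.58 to −0.203). T and NK cell markers were low as well, with medians of −1.77 in BMDC, −1.39 in BMDC with LPS, −1.82 in TolDC and −1.58 in TolDC with LPS. B cell markers had medians of −0.94, −0.29, −1.07 and −0.44 in that order, macrophage markers of −0.0099, −0.29, −0.078 and −0.24, and conventional dendritic cell markers of −0.045, −0.067, 0.078 and 0.051. Fewer cells of other marrow types in these libraries may be the cause, although an enrichment of CD11c-bearing cells would remove most of them. Cell cycle genes were lower too in BMDC (median −0.27, 30 of 32 genes) and in BMDC with LPS (−0.53, 29 of 32). After the trends of GC content and length were removed, 93.75% of the 288 genes (270) stayed at least 1.5-fold lower, which argues against that bias. A shared day, culture or sorting run of the libraries numbered 1 is not given in the labels and stays open, and no biological explanation was tested.

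Libraries 2 and 3 vary less from each other, which narrows the spread, so leaving out library 1 cannot tell if calls depend on it. A fit without the libraries numbered 1 kept 91.2% of the calls of the difference between responses (511 lost, 893 gained) and 94.1% to 95.9% of the others. The neutrophil (median −1.26), mast cell (1.08) and T and NK cell (0.84) lists then passed in the comparison of unstimulated TolDC with BMDC, as they did with the replicate block (−1.28, 1.04 and 0.90), but not with the libraries numbered 2 and 3 summed. With all libraries, 0 of 8 mast cell markers were called, and the 3 lists had an adjusted p = 0.975, 0.975 and 0.974 with an estimated correlation.

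Cyp24a1 was at 13.1 CPM in BMDC replicate 3, against 0 and 0.0324 CPM in replicates 1 and 2. Over 47 other genes at least 8-fold higher in TolDC than in BMDC replicate 1, which takes no part in the difference, the excess of BMDC replicate 3 over replicate 2 was 1.02% of the TolDC level (95% bootstrap interval 0.517% to 1.57%), with 37 of 47 genes above replicate 2. For Cyp24a1 it was 0.743%, and the same difference between BMDC with LPS replicates 3 and 2 over these genes was −0.313%. RNA or reads of TolDC in the BMDC replicate 3 library may therefore account for these counts, and where they entered stays open. No biological explanation was tested.

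For the comparisons of 3 with 3 libraries, 10 splits are too few for a share under 0.05. The real splits, fitted to 6 libraries, gave 9210 genes for LPS in BMDC, 9326 for LPS in TolDC, 8024 for TolDC without LPS and 8639 with LPS, and the highest of the other splits gave 0 in each. Replicates varied more than counting predicts, with a chi-square per degree of freedom of 1.34 to 2.24 between libraries 2 and 3 and of 4.93 to 10.9 between library 1 and the others.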
